A study of Mus musculus with 4 samples.

How the data were processed

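Brain cells of P12 mice were digested with an enzyme kit and sorted for CD31 and CD140b, and libraries were made with Chromium v3.1 reagents, per the labels' protocols. The deposited values are UMI counts per gene and barcode, whole numbers with no normalization, from Cell Ranger 3.1.0, per the file headers. Cell Ranger 3.1.0, Seurat (no version given) and the genome build mm10 are named per the submitters' processing notes, without their roles. For each library a matrix of barcodes called as cells and a matrix of all barcodes were used, with 31053 genes in each, of which 30934 had their identifier in GENCODE M21, the source of gene coordinates. Cell names and clusters of the authors were not analysed here.

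Called barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 6846 of 8755 in WT 1, 6918 of 8480 in WT 2, 4409 of 5514 in Alk5iEKO 1 and 7215 of 8824 in Alk5iEKO 2. Doublets were scored against simulated doublets and the highest scores removed at 0.8% per 1000 barcodes, 479, 469, 194 and 509 cells in the same order. Counts scaled to 10000 per cell were log-transformed, and 2000 highly variable genes, 30 principal components and 20 nearest neighbours fed Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9). Clusters were named by the scores of marker lists, a named cluster needing at least 3 detected markers and its own markers among its 10 leading genes, and were left unnamed where 2 classes scored alike. Endothelial-like cells were clustered again on highly variable genes without those called between genotypes in all endothelial-like cells. They were named by subtype lists. The subtype scores left out called markers too, while the check of the 10 leading genes used all markers. The rule for naming subtypes was tightened after the first sub-clusters were seen. Names end in "-like" because they rest on transcripts alone.

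Counts were summed per library over the cells of a class with at least 20 cells in every library, so that the library is the replicate (n = 2 per group). Genes were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). The difference of the genotype effect between endothelial-like and pericyte-like cells was tested as an interaction with library as block. 35 gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with adjustment over the lists. The same test with an estimated correlation and fry were run as alternatives. The counts adjusted over the list alone use the single-gene p-values with the adjustment limited to the members of that list. Shares of cells per class or subtype were tested with edgeR on numbers of cells with the library's total as size. R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. CPM values are summed counts scaled to the TMM-adjusted total of the genes kept by the filter, for each library and class. Those of Xist and the Y-linked genes are scaled to the unadjusted total of all genes.

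The samples, groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. By the rule for named genes the text names the 10 largest rises and 10 largest falls in endothelial-like cells. It names 5 of each in pericyte-like cells and in the test between classes, and only some of those 5 in subtypes. These are genes past the threshold with a mean of at least 20 CPM over the 4 libraries and both Alk5iEKO libraries beyond both WT libraries. Predicted gene models, Xist, Tsix, Y-linked and hemoglobin genes were left out of these. Where fewer than 5 genes passed, some or all of the 5 genes with the smallest p-values are named. The text also names up to 4 genes of each list described, by smallest p, and genes of the TGFβ pathway. Fn1, Bgn and S100a6 in the test between classes, and the sex-linked genes, were chosen after their values were seen.

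The tests of genes were run on simulated counts with the means and library sizes of the real libraries and 200 changed genes. Removal of doublets, clustering and naming were not simulated. In the simulation of endothelial-like cells 9.72% of called genes were wrong calls, with 16.4%, 79.1% and 100% of changed genes recovered at 1.5-fold, 2-fold and 4-fold. In pericyte-like cells 10.1% of calls were wrong with 19.4%, 94.0% and 100% recovered, and in the interaction 12.0% with 0%, 22.4% and 100%. For the interaction both classes were drawn independently, with no library effect shared between them. The values for the interaction therefore do not show how the real test with library as block performs. Wrong calls exceeded the nominal 5% in every class and subtype simulated, from 5.66% in proliferating cells to 16.7% in smooth-muscle-like cells. At 2-fold 35.8% of changed genes were recovered in fibroblast-like and 13.4% in neuron-like cells. In the simulation of lists camera called a list of raised genes at the preset correlation (adjusted p = 1.85e-20) and missed it with an estimated correlation (adjusted p = 0.675). Genes were drawn independently there, so it cannot show how often the preset gives false calls for correlated genes. The estimated correlation was 0.22 for the interferon response list in endothelial-like cells. For shares, a class raised 3-fold was called in 47 of 50 runs, with 7 calls among unchanged classes. Those runs used set proportions and a common spread between libraries, not the real shares and their spread.

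Alternatives were DESeq2 1.42.0 in place of edgeR, its size factors, no filter on low counts, each library left out in turn, doublets kept, at most 5% mitochondrial UMIs, subtraction of free RNA measured in barcodes with at most 100 UMIs, cells thinned to an equal median UMI count within each class, capillary cells only, no proliferating cells, equal numbers of endothelial-like cells and other clustering resolutions. Leaving out cells with over 1% hemoglobin UMIs, removing each library's mean before sub-clustering and naming every sub-cluster by its highest score were added after the data were seen. A fit with 1 library in a group assumes that it varies like the other group. Classes and subtypes under the minimum number of cells, microglia-like and choroid-plexus-like among them, were not tested for genes.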

Results

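Brain cells of mice on postnatal day 12 (P12), sorted for CD31 and CD140b, which mark endothelial and mural cells, were profiled as 4 droplet RNA libraries. 2 libraries came from mice labelled Tgfβr1 I/I (WT) and 2 from mice labelled Alk5iEKO, an inducible endothelial knockout of Alk5, the type I TGFβ receptor encoded by Tgfbr1. The total unique molecular identifier (UMI) count over the called barcodes was 54638142 in WT 1, 71876682 in WT 2, 46479209 in Alk5iEKO 1 and 73748854 in Alk5iEKO 2. After filters and removal of doublets 6367, 6449, 4215 and 6706 cells were kept in the same order, with median UMI counts per passing barcode of 7034, 9139, 9058 and 8556. The labels do not say that the libraries come from separate animals, so each p-value measures only the spread between these libraries. Values per group are means over 2 libraries, in UMI counts summed over the cells of a class and scaled to the library's TMM-adjusted total (CPM), and log2 fold changes are Alk5iEKO over WT with their standard error.

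Cells were named by marker genes as endothelial-like (3522, 3730, 1952 and 3415 cells in WT 1, WT 2, Alk5iEKO 1 and Alk5iEKO 2), pericyte-like (1187, 856, 1275 and 2237), smooth-muscle-like (346, 271, 230 and 374), fibroblast-like (508, 288, 340 and 297), astrocyte-like (494, 206, 253 and 133) and neuron-like (188, 252, 34 and 87). Microglia-like cells were nearly all in WT 2, with 746 cells against 1 in WT 1, 11 in Alk5iEKO 1 and 28 in Alk5iEKO 2, so their genes were not tested between genotypes. WT 2 also stood apart in sex-linked transcripts. Xist, expressed from the inactive X chromosome, had 811 CPM in endothelial-like cells of WT 1, 904 in Alk5iEKO 1 and 749 in Alk5iEKO 2, against 8.56 in WT 2. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 264 CPM in WT 2 and 127, 130 and 140 in the other libraries in that order. In WT 1, 3.07% of endothelial-like cells (95% Wilson interval 2.55% to 3.69%) held a UMI of both Xist and a Y-linked gene, where 21% would if the detections were independent. The share was 3.23% in Alk5iEKO 1 (interval 2.53% to 4.11%) and 3.51% in Alk5iEKO 2 (interval 2.95% to 4.19%). Cells with Xist alone made up 48.0%, 46.3% and 39.8% in WT 1, Alk5iEKO 1 and Alk5iEKO 2. Those with Y-linked genes alone made up 38.1%, 40.0% and 45.2%, so these libraries held cells of both sexes. In WT 2 the values were 0.483% and 88.3%. Sex thus differed between the WT libraries and in part between the genotypes.

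The first comparison asks which transcripts of brain endothelial cells depend on endothelial Alk5. Tgfbr1 itself (ENSMUSG00000007613, mm10 chromosome 4, 47353222 to 47414931) had 24.6 and 28.8 CPM in WT and 25.8 and 23.1 CPM in Alk5iEKO endothelial-like cells, a log2 fold change of −0.13 ± 0.12 (adjusted p = 0.594). The labels do not say which part of the gene is deleted, so this level is no measure of the deletion. Nor do they say whether WT mice received the drug that induces the knockout, so an effect of the drug cannot be told apart from one of the deletion. Htra3, a secreted serine protease (ENSMUSG00000029096, mm10 chromosome 5, 35652023 to 35679782), went from 224 to 4.71 CPM, a log2 fold change of −5.60 ± 0.36 (adjusted p = 0.00172). The largest rise was in Zbtb16, a zinc-finger transcription factor (ENSMUSG00000066687, mm10 chromosome 9, 48654297 to 48836222), from 1.29 to 43.9 CPM, or 5.11 ± 0.17 (adjusted p = 6.01e-04). In total 1214 of 13760 tested genes passed, 645 higher and 569 lower in Alk5iEKO.

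Among the other genes with the largest falls were Htra1, a protease related to Htra3 (−3.67 ± 0.60), Adamtsl2, a secreted protein that binds microfibrils (−3.49 ± 0.12), Mfap2, a microfibril component (−3.07 ± 0.31), and Megf6 (−2.87 ± 0.18). Htra1 had 153 CPM in WT 1 and 44.9 in WT 2. Ackr2, a chemokine scavenging receptor, fell by 4.44 ± 0.15, Stra6, a retinol transporter, by 4.05 ± 0.16, and Ctsw, which encodes a cathepsin, by 4.53 ± 0.25. Lmntd1 (−3.32 ± 0.15) and AU021092 (−2.80 ± 0.14) complete the 10 largest falls. The rises included Mt1, a metallothionein (3.35 ± 0.21, from 10.5 to 106 CPM), Lcn2, an acute-phase protein that binds iron carriers (2.95 ± 0.11, from 12.4 to 96.5 CPM), and Ackr1, a chemokine receptor of venules (2.59 ± 0.17). Gpihbp1, the endothelial anchor of lipoprotein lipase, rose by 2.60 ± 0.10, and the calcium-binding protein gene S100a6 by 2.46 ± 0.11. Phlda3 (3.19 ± 0.26), the kinase gene Tnik (2.81 ± 0.12), Galnt15 (2.58 ± 0.11) and the sulfotransferase gene Sult1a1 (2.54 ± 0.12) complete the 10 largest rises. Adjusted p-values of these 20 genes lay between 6.01e-04 and 0.0214. With Alk5iEKO 1 or Alk5iEKO 2 left out 0 genes passed in edgeR, with 2526 and 2167 at an unadjusted p under 0.05, and with WT 1 or WT 2 left out 1919 and 2703 passed. DESeq2 with all libraries called 1587.

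**Figure D1:**
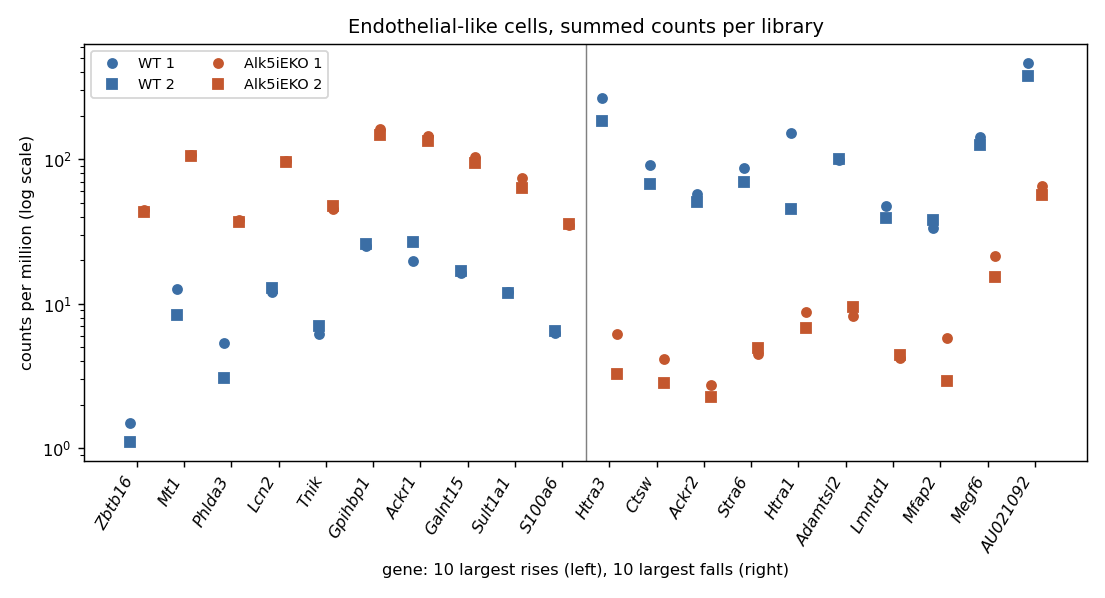
CPM in endothelial-like cells (log axis), 1 point per library, for the 10 genes with the largest rises and the 10 with the largest falls in Alk5iEKO. Htra3 had 265 and 183 CPM in the WT libraries and 6.16 and 3.26 in the Alk5iEKO libraries.

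TGFβ pathway genes moved in both directions in endothelial-like cells. Of 24 tested receptors, ligands and Smads, Tgfbr2, the type II receptor (0.61 ± 0.08, from 271 to 413 CPM, adjusted p = 0.0129), and Tgfbr3, the accessory receptor betaglycan (0.98 ± 0.15, adjusted p = 0.0177), rose. Ltbp4, which stores latent TGFβ in the matrix (−1.04 ± 0.11, adjusted p = 0.00628), and Itgav, an integrin subunit (−0.82 ± 0.18, adjusted p = 0.0482), fell, and 20 did not pass. Adjusted over the list alone 2 rose and 3 fell, and the list did not pass as a set (camera adjusted p = 0.771). Acvrl1, which encodes the receptor ALK1 (0.02 ± 0.08), and Eng, its co-receptor (−0.18 ± 0.10), were among those not past the threshold. Of 30 tested TGFβ/Smad target genes 8 fell and 5 rose, and adjusted over the list alone 11 fell and 7 rose. Pmepa1, a feedback inhibitor of the pathway, fell by 2.61 ± 0.13, the cell-cycle inhibitor gene Cdkn2b by 2.50 ± 0.18 and the fibronectin gene Fn1 by 1.45 ± 0.09, whereas Timp3, a protease inhibitor, rose by 1.56 ± 0.14. The target list did not pass as a set (adjusted p = 0.368).

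Of 17 tested target genes of BMP9 and ALK1, 4 rose and 0 fell in edgeR, and adjusted over the list alone 4 rose and 1 fell. They were Atoh8 (1.52 ± 0.21), Id3 (0.75 ± 0.11), Gja4 (0.74 ± 0.13) and Id1 (0.52 ± 0.10), and the list did not pass as a set (adjusted p = 0.598). Of 53 genes of basement membrane and extracellular matrix 9 fell and 6 rose, adjusted over the list alone 12 fell and 8 rose, and the set did not pass (adjusted p = 0.444). The proteoglycan gene Bgn fell by 2.75 ± 0.11 and Nid1, a basement membrane linker, by 1.35 ± 0.09. Of 19 Notch pathway genes Mfng (−0.83 ± 0.10) and Hes1 (−1.19 ± 0.23) fell (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.341). Of 18 VEGF pathway genes Flt4 (−0.82 ± 0.09), Flt1 (−0.67 ± 0.13) and Nr4a2 (−0.54 ± 0.12) fell (5 lower and 3 higher adjusted over the list alone, camera adjusted p = 0.430).

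Many interferon response genes rose in endothelial-like cells. Of 34 tested 19 rose and 0 fell in edgeR, and adjusted over the list alone 26 rose and 0 fell. Rsad2, an antiviral enzyme (2.02 ± 0.20), Ifit1 (1.44 ± 0.13), the class I antigen gene H2-K1 (1.06 ± 0.12) and Bst2 (0.999 ± 0.12) were among them. The list passed with the preset correlation of camera (adjusted p = 2.19e-13) and not with an estimated correlation (adjusted p = 0.676 with an estimated correlation). Of 27 genes of leukocyte adhesion and inflammation 13 rose and 0 fell, and adjusted over the list alone 19 rose and 1 fell. Beside Lcn2 and Ackr1 they included Ptgs2, which makes prostaglandins (2.52 ± 0.18), and the chemokine gene Cxcl1 (1.93 ± 0.16), with an adjusted p for the list of 4.50e-08, and adjusted p = 0.676 with an estimated correlation. Of 27 venous endothelial markers 9 rose and 2 fell (14 and 3 adjusted over the list alone), among them Cp, which encodes ceruloplasmin (1.89 ± 0.10). The list passed upwards (adjusted p = 2.92e-05, and adjusted p = 0.845 with an estimated correlation). Cells named venous made up a mean of 10.2% of endothelial-like cells in WT and 31.6% in Alk5iEKO. A rise within cells cannot be told apart here from a change in subtype mix.

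More genes of the blood-brain barrier and of capillary identity fell than rose in the sums over all endothelial-like cells. Cells named capillary made up a mean of 48.5% of these cells in WT and 9.28% in Alk5iEKO. The sums cannot tell a lower level within cells from a change in subtype mix. Of 30 barrier transporters 10 fell and 3 rose, and adjusted over the list alone 15 fell and 4 rose (adjusted p = 1.45e-04, and adjusted p = 0.845 with an estimated correlation). The transferrin receptor gene Tfrc fell by 1.24 ± 0.09, from 1565 to 662 CPM, the lipid transporter gene Mfsd2a by 1.26 ± 0.09 and the organic anion transporter gene Slc22a8 by 0.91 ± 0.08, whereas Slc2a1, the glucose transporter, rose by 0.61 ± 0.09. Of 22 capillary markers 8 fell and 1 rose, and adjusted over the list alone 13 fell and 4 rose (adjusted p = 0.00174, and adjusted p = 0.845 with an estimated correlation). Spock2, a matrix proteoglycan, fell by 2.26 ± 0.14 and Itih5 rose by 1.88 ± 0.09. Of 19 targets of Wnt/β-catenin signalling in brain endothelium 7 fell and 0 rose in edgeR, and adjusted over the list alone 11 fell and 2 rose (adjusted p = 0.00564, and adjusted p = 0.676 with an estimated correlation). They included Notum, a Wnt inhibitor (−1.35 ± 0.18), Apcdd1, another Wnt inhibitor (−1.28 ± 0.22), Fgfbp1 (−0.84 ± 0.13) and Rflnb (−0.75 ± 0.10). The Wnt list no longer passed without Alk5iEKO 2 (adjusted p = 0.0566), with adjusted p from 0.00112 to 0.676 over all its alternatives.

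**Figure D2:**
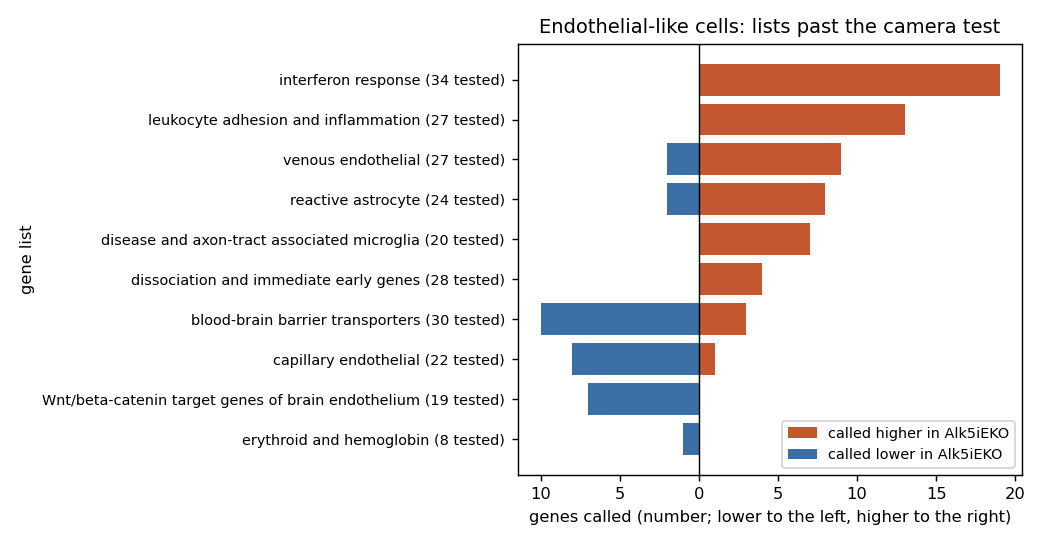
Numbers of genes called higher and lower in Alk5iEKO endothelial-like cells in each of the 10 gene lists that passed camera with its preset correlation. The interferon response list held 19 genes called higher and 0 called lower.

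The remaining lists that passed in endothelial-like cells hold genes with other known roles too. Of 24 reactive astrocyte markers 8 rose and 2 fell (11 and 2 adjusted over the list alone), with adjusted p = 3.76e-04, and adjusted p = 0.676 with an estimated correlation. The members that rose included Lcn2, Cp, the intermediate filament gene Vim (1.04 ± 0.09) and Cd109, a membrane protein known to bind TGFβ (2.36 ± 0.17). Of 20 markers of disease-associated microglia 7 rose and 0 fell (10 and 1 adjusted over the list alone), with adjusted p = 0.00107, and adjusted p = 0.723 with an estimated correlation. Apoe, a lipid carrier, rose by 1.23 ± 0.09 and the tetraspanin gene Cd9 by 1.17 ± 0.13, and the list missed the threshold without WT 1 (adjusted p = 0.0650, from 4.55e-06 to 0.723 over all its alternatives). Of 28 genes of dissociation and immediate early response 4 rose and 0 fell (6 and 1 adjusted over the list alone), with adjusted p = 0.0185, and adjusted p = 0.676 with an estimated correlation. The chaperone gene Hspa8 rose by 0.56 ± 0.08 and Zfp36, which destabilises messenger RNA, by 0.90 ± 0.15, and the list missed the threshold without WT 2 (adjusted p = 0.194) and without Alk5iEKO 1 (0.0547), from 0.00574 to 0.676 over all its alternatives. Of 8 erythroid genes 1 fell and 0 rose, and adjusted over the list alone 7 fell and 1 rose (adjusted p = 0.00688, and adjusted p = 0.845 with an estimated correlation). Endothelial-like cells with over 1% hemoglobin UMIs numbered 27 in WT 1, 24 in WT 2, 2 in Alk5iEKO 1 and 4 in Alk5iEKO 2, and without them 1212 genes passed.

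The second comparison asks how endothelial subtypes differed, since the labels name endothelial enrichment. Cells named capillary made up 44.1% and 52.8% of endothelial-like cells in WT and 9.89% and 8.67% in Alk5iEKO, a log2 fold change of the share of −2.39 ± 0.19 (adjusted p = 0.00106). Cells named venous made up 6.93% and 13.5% in WT and 30.7% and 32.4% in Alk5iEKO (1.62 ± 0.37, adjusted p = 0.0284). Of the venous sub-clusters 1 with a score of 1.42 held 219 and 446 WT and 255 and 470 Alk5iEKO cells, and the other, with a score of 0.433, held 25 and 59 against 345 and 637. The venous share no longer passed with doublets kept (0.43, adjusted p = 0.913), at 0.5 times (0.92, 0.415) or 2 times the resolution (1.05, 0.0875), or without Alk5iEKO 1 (1.66, 0.140) or Alk5iEKO 2 (1.59, 0.116). Through the check of leading genes the names rest partly on genes that themselves fell or rose in Alk5iEKO. Examples are Spock2, Mfsd2a and Tfrc for capillary cells and Lcn2 and Ackr1 for venous cells. With each library's own mean removed before clustering, a step chosen after seeing the data, the capillary share had −0.24 (adjusted p = 0.079) and the venous share 0.26 (adjusted p = 0.42). This step also removes true differences in composition, since each library has 1 genotype. It therefore cannot tell a change in composition from a shift in expression at an unchanged composition. Tip-like cells had 13.9% ± 0.22 (SD, n = 2) in WT and 18.8% ± 0.83 in Alk5iEKO, arterial cells 7.96% ± 1.67 and 7.81% ± 0.69, and proliferating cells 5.97% ± 0.13 and 5.88% ± 2.16, with adjusted p-values of 0.0657, 0.985 and 0.985. The arterial share passed as higher with all highly variable genes (2.03, adjusted p = 0.00157) and with library means removed (0.59, adjusted p = 0.0426). No subtype name was given to 22.5% of endothelial-like cells in WT 1, 4.37% in WT 2, 27.3% in Alk5iEKO 1 and 25.9% in Alk5iEKO 2, under a naming rule tightened after the first sub-clusters were seen. They include a sub-cluster of 18 and 51 WT and 489 and 817 Alk5iEKO cells that scored highest as capillary. Its 10 leading genes held 0 capillary markers and 3 arterial ones, Cxcl12, Glul and Gja4, so its name stays open. With all highly variable genes the arterial share was 38.3% and 34.8% in Alk5iEKO, and 1.64% and 1.58% were unnamed. Another unnamed sub-cluster that scored highest as capillary held 644 and 1 WT and 4 and 0 Alk5iEKO cells. With every sub-cluster named by its highest score, an alternative added after seeing the data, capillary cells made up 62.9% and 54.2% in WT and 35.1% and 32.6% in Alk5iEKO (−0.79, adjusted p = 0.0229). These shares count the sub-cluster led by arterial markers as capillary.

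**Figure D3:**
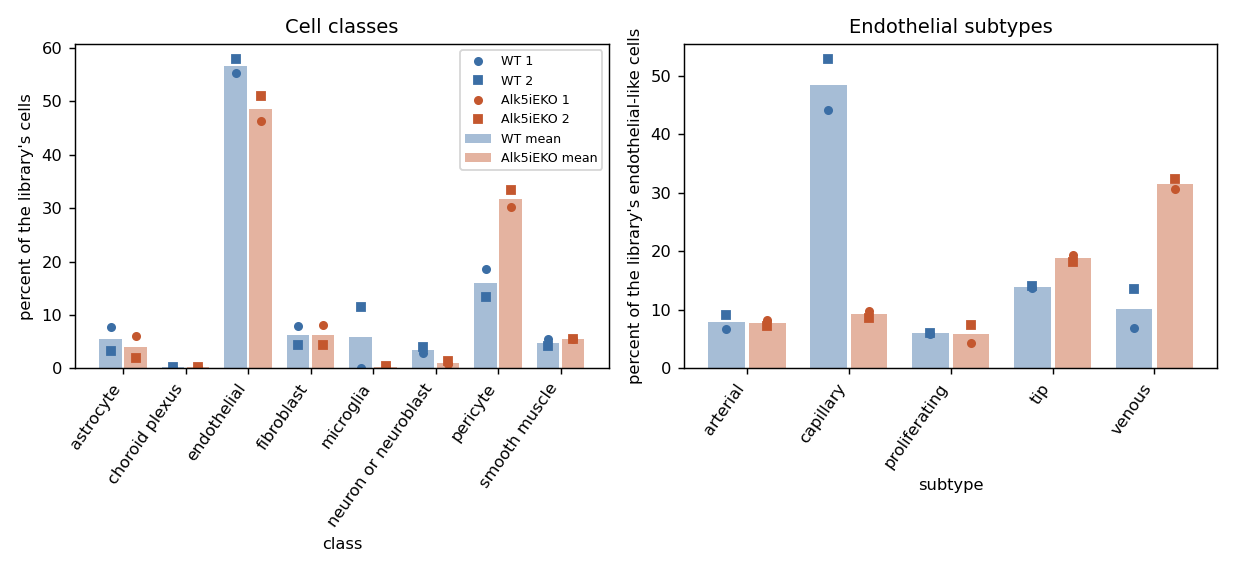
Shares of cells by class (of all cells) and by endothelial subtype (of endothelial-like cells), in percent, with bars for group means and 1 point per library. The capillary share was 44.1% and 52.8% in WT and 9.89% and 8.67% in Alk5iEKO, and the pericyte share 18.6% and 13.3% against 30.2% and 33.4%.

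Within subtypes, several of the same genes led. Zbtb16 rose in arterial (4.29 ± 0.29, adjusted p = 0.00173) and venous cells (3.70 ± 0.18, adjusted p = 0.00136), and Mt1 in venous (3.25 ± 0.20) and tip-like cells (4.02 ± 0.18). Stra6 fell in arterial (−4.94 ± 0.64) and capillary cells (−3.88 ± 0.51), and Mfap2 in both (−4.09 ± 0.26 and −3.18 ± 0.37). Htra3 fell in tip-like (−6.00 ± 0.24, adjusted p = 2.99e-05) and proliferating cells (−6.57 ± 0.36, adjusted p = 3.15e-04), and had 47.5 and 39.4 CPM in WT and 0 and 1.06 CPM in Alk5iEKO arterial cells. Within a subtype the genotypes partly lay in different sub-clusters. Of the tip-like sub-clusters 1 held 26 and 58 WT and 316 and 541 Alk5iEKO cells and another 402 and 369 against 23 and 21. A capillary sub-cluster with a median UMI count of 2967 held 396 of 1554 and 173 of 1971 capillary cells in WT and 111 of 193 and 127 of 296 in Alk5iEKO. Another 2 held mostly 1 WT library each, with 1027 cells of WT 1 and 10 of WT 2, and with 107 and 1311. The remaining capillary sub-cluster held 24 cells of WT 1, 477 of WT 2, 33 of Alk5iEKO 1 and 105 of Alk5iEKO 2. Tip-like cells had 1533 genes past the threshold of 11152 tested (734 higher, 799 lower). Angpt2, a ligand that destabilises vessels, rose in proliferating cells (4.56 ± 0.31), as did Gpihbp1 (5.23 ± 0.38), and Spock2 (−3.66 ± 0.14) and Bgn (−3.58 ± 0.29) fell there. Igfbp3 rose in capillary (5.06 ± 0.55) and venous cells (2.95 ± 0.23), and Ackr1 in capillary (4.70 ± 0.58) and tip-like cells (3.49 ± 0.28). In venous cells the elastin gene Eln (−2.55 ± 0.26) and the growth factor gene Pdgfa (−2.34 ± 0.17) fell.

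The numbers past the threshold were 593 of 10344 tested in proliferating, 394 of 11334 in venous, 208 of 11303 in capillary and 147 of 9808 in arterial cells. Without WT 2 the counts were 1398, 1294, 1100 and 822 in the same order and 2464 in tip-like cells. Without Alk5iEKO 1 they were 130, 0, 0 and 0 and 500 in tip-like cells, with 1100, 1129 and 809 genes at an unadjusted p under 0.05 behind the counts of 0 in edgeR. DESeq2 with all libraries called 391, 405, 393 and 142, and 1157 in tip-like cells.

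The third comparison asks how pericytes, which lie outside the endothelial knockout that the labels name, differed between the genotypes. The chemokine genes Cxcl1 (ENSMUSG00000029380, mm10 chromosome 5, 90891241 to 90893115) and Ccl2 rose by 4.59 ± 0.28 (from 1.83 to 43.6 CPM, adjusted p = 0.00350) and 4.28 ± 0.27 (from 10.03 to 194 CPM, adjusted p = 0.00350). The collagen gene Col1a1 rose by 2.69 ± 0.17, S100a6 by 2.56 ± 0.10 and Emp1 by 1.99 ± 0.14. Casq2, a calcium-binding protein of muscle stores (ENSMUSG00000027861, mm10 chromosome 3, 102086415 to 102146514), fell by 2.21 ± 0.10, from 103 to 22.4 CPM (adjusted p = 0.00118). Pla2g7 (−1.84 ± 0.13), the neuropeptide receptor gene Adcyap1r1 (−1.83 ± 0.29), the Wnt modulator gene Sfrp2 (−1.78 ± 0.17) and Col28a1 (−1.71 ± 0.18) were the other largest falls. One pericyte cluster held 71 and 27 WT and 560 and 1151 Alk5iEKO cells. The median UMI count of pericyte-like cells was 4959 and 6180 in WT and 8996 and 8125 in Alk5iEKO, and with cells thinned to an equal median 851 genes passed. In total 996 of 12532 tested genes passed, 612 higher and 384 lower. With doublets kept 665 passed, and 528 of the 996 were among them in the same direction. With Alk5iEKO 1 left out 0 genes passed in edgeR (1949 at an unadjusted p under 0.05), with Alk5iEKO 2 left out 1, and with WT 1 or WT 2 left out 1739 and 2131. DESeq2 with all libraries called 1079.

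Of 54 tested genes of basement membrane and extracellular matrix 20 rose and 3 fell in pericyte-like cells, and adjusted over the list alone 23 rose and 7 fell (adjusted p = 0.00334, and adjusted p = 0.471 with an estimated correlation). Fn1 rose by 1.46 ± 0.12, Timp3 by 1.02 ± 0.08 and Bgn by 0.79 ± 0.07. Of 29 TGFβ/Smad target genes 8 rose and 1 fell (9 and 2 adjusted over the list alone), with adjusted p = 0.0273, and adjusted p = 0.471 with an estimated correlation. The transcription factor gene Junb (1.20 ± 0.08), Fn1 and Timp3 rose, while Smad7, a feedback inhibitor, fell by 1.08 ± 0.22. Of 21 genes of leukocyte adhesion and inflammation 8 rose and 0 fell (10 and 1 adjusted over the list alone), with adjusted p = 8.73e-04, and adjusted p = 0.425 with an estimated correlation. Beside Cxcl1 and Ccl2 they included the NF-κB genes Nfkb2 (1.20 ± 0.15) and Nfkbia (0.68 ± 0.08). Of 20 integrin and focal adhesion genes 4 rose and 0 fell (7 and 1 adjusted over the list alone), with Itga6 at 1.10 ± 0.15 and Itga5 at 0.78 ± 0.14 (adjusted p = 0.0213, and adjusted p = 0.607 with an estimated correlation).

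The lists of energy metabolism genes passed upwards as sets in pericyte-like cells, which had more UMIs per cell in Alk5iEKO, though not with an estimated correlation. Of 18 glycolysis genes 9 rose and 1 fell (12 and 1 adjusted over the list alone), among them the lactate exporter gene Slc16a3 (1.39 ± 0.15), Pfkp (0.94 ± 0.11), Gapdh (0.80 ± 0.10) and Tpi1 (0.69 ± 0.08). The list had adjusted p = 0.00153, and adjusted p = 0.425 with an estimated correlation. Of 52 nuclear genes of oxidative phosphorylation 3 rose and 0 fell, and adjusted over the list alone 16 rose and 0 fell (adjusted p = 1.65e-06, and adjusted p = 0.425 with an estimated correlation), with Uqcrh at 0.34 ± 0.07 and Ndufb5 at 0.36 ± 0.08. Of 28 genes of dissociation and immediate early response 7 rose and 0 fell (10 and 0 adjusted over the list alone), with Egr1, an immediate early transcription factor, at 1.44 ± 0.14 (adjusted p = 0.00220, and adjusted p = 0.425 with an estimated correlation). Of 20 markers of disease-associated microglia 4 rose and 1 fell, overall and adjusted over the list alone (adjusted p = 0.0273, and adjusted p = 0.607 with an estimated correlation). They included the lectin gene Lgals1 (1.26 ± 0.09), the lipid-binding protein gene Fabp5 (1.25 ± 0.08) and Cd9 (1.44 ± 0.14).

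Some pericyte identity genes fell in pericyte-like cells. Of 21 tested 7 fell and 0 rose in edgeR, and adjusted over the list alone 11 fell and 0 rose (adjusted p = 0.00153, and adjusted p = 0.487 with an estimated correlation). Art3 fell by 0.98 ± 0.10, Atp13a5 by 0.71 ± 0.09, Cox4i2 by 0.62 ± 0.08 and Pdgfrb, which encodes the receptor CD140b used in the sort, by 0.46 ± 0.07. Of 17 Notch pathway genes Dll4, a ligand (−1.82 ± 0.22), and Nrarp, a feedback target (−1.05 ± 0.20), fell and 0 rose in edgeR (5 and 0 adjusted over the list alone), with adjusted p = 0.0109, and adjusted p = 0.425 with an estimated correlation. Of 26 barrier transporters 5 fell and 0 rose (8 lower and 1 higher adjusted over the list alone), with Slc22a8 at −1.15 ± 0.09. Of 22 capillary markers 6 fell and 1 rose (8 lower and 4 higher adjusted over the list alone), with Spock2 at −1.94 ± 0.14. Carried endothelial RNA was estimated from the median over endothelial marker genes. The estimate came to 177% of the WT pericyte level of Spock2, 172% of that of Mfsd2a and 4.26% of that of Slc22a8. For Spock2 and Mfsd2a it exceeds the measured level, so it is too high for them. The barrier and capillary lists each had adjusted p = 0.00153, and adjusted p = 0.425 with an estimated correlation. Endothelial genes have a background in pericyte-like cells of 2%, 1.96%, 1.54% and 1.99% of their endothelial level in WT 1, WT 2, Alk5iEKO 1 and Alk5iEKO 2.

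The genotype effect was compared between endothelial-like and pericyte-like cells by an interaction test with library as block. It differed in 2626 of 14495 tested genes, in 1209 of them higher in endothelial-like cells and in 1417 lower. Fn1 and Bgn fell in endothelial-like and rose in pericyte-like cells, and their effects differed by −2.92 (adjusted p = 9.11e-18) and −3.55 (adjusted p = 1.06e-18). The largest differences were Htra3 (−5.90 ± 0.21), Syt12 (−3.62 ± 0.19), Chp2 (−3.57 ± 0.14), Bpgm, a red-cell glycolytic enzyme (−3.57 ± 0.13), and Adamtsl2 (−3.57 ± 0.35), and on the other side Enpp2, which makes lysophosphatidic acid (3.34 ± 0.36), Mt1 (3.1 ± 0.11), Adgrg1 (2.89 ± 0.38), Sult1a1 (2.84 ± 0.11) and the interferon-induced gene Ifitm1 (2.68 ± 0.12). S100a6 rose in both classes, and its difference did not pass (−0.10, adjusted p = 0.667). Of 11972 genes tested in both classes 70 were called higher in both and 45 lower in both, against 24.4 and 12.9 for independent lists. The same libraries lie behind both sets of calls, so they are not independent. A further 26 were higher in endothelial-like and lower in pericyte-like cells and 40 the reverse. DESeq2 called 1074 differences.

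**Figure D4:**
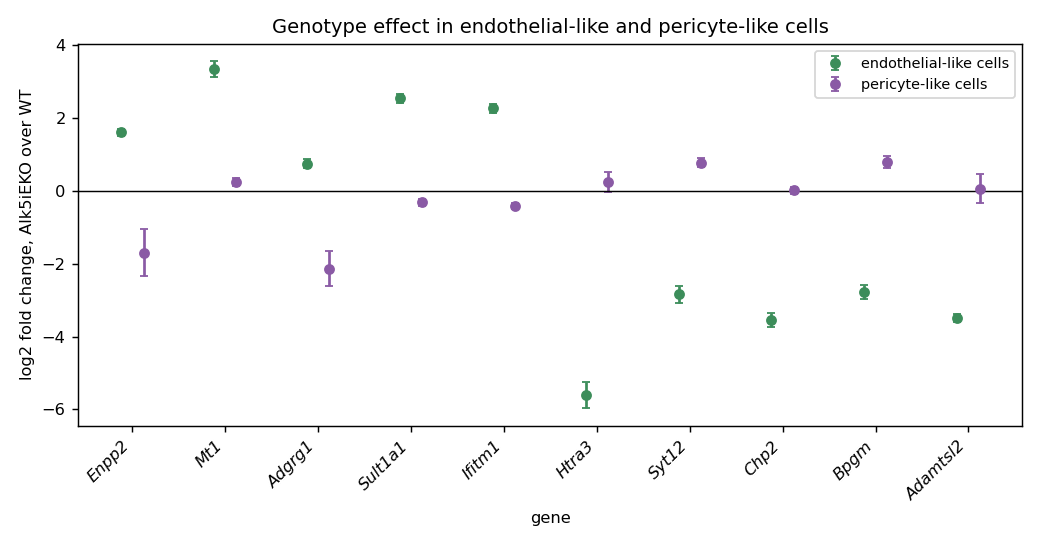
Log2 fold changes of Alk5iEKO over WT with their standard error (bars) in endothelial-like and pericyte-like cells for the 10 genes with the largest difference between the classes. Htra3 and Enpp2 had the largest differences on either side, −5.90 and 3.34.

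The other classes held few cells and few calls. In smooth-muscle-like cells 1 of 10769 genes passed, Ptgis, which encodes prostacyclin synthase and rose by 1.64 ± 0.13, from 55.7 to 173 CPM (adjusted p = 0.0342). Tfrc (−1.70 ± 0.17), Car4 (1.06 ± 0.12), Eln (1.30 ± 0.15) and Sult1a1 (1.84 ± 0.21) had the next smallest p-values there and did not pass (adjusted p = 0.0732 for each). In astrocyte-like cells 3 of 10523 tested genes passed, 2 higher and 1 lower. The complement gene C4b (1.78 ± 0.16, adjusted p = 0.00681) was among the higher, and the endothelin receptor gene Ednrb fell by 1.57 ± 0.16 (adjusted p = 0.0102). With doublets kept 0 genes passed in astrocyte-like cells in edgeR, with 906 at an unadjusted p under 0.05, and DESeq2 called 57 with doublets removed. In fibroblast-like cells 0 of 11428 genes passed in edgeR, with 497 at an unadjusted p under 0.05 and 9 called by DESeq2, and the smallest p-values were of Igfbp6 (1.17 ± 0.15) and Apod (1.15 ± 0.15), each with adjusted p = 0.726. In neuron-like cells 0 of 9468 genes passed in edgeR, with 378 at an unadjusted p under 0.05 and 3 called by DESeq2. The smallest p-values there were of Tm4sf1 (3.67 ± 0.46), Col4a1 (2.65 ± 0.36) and Rgs5 (2.40 ± 0.33), genes of endothelial and mural cells (adjusted p = 0.177).

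As sets, 28 tested TGFβ/Smad target genes rose in smooth-muscle-like cells (10 higher and 1 lower adjusted over the list alone, adjusted p = 1.47e-06, and adjusted p = 0.526 with an estimated correlation), while 0 of them passed singly in edgeR. In smooth-muscle-like cells 7 lists passed in all, in fibroblast-like and astrocyte-like cells 8 each and in neuron-like cells 7, and 0 of these held with an estimated correlation. In astrocyte-like cells 17 reactive astrocyte markers rose as a set (5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00962, and adjusted p = 0.864 with an estimated correlation). In neuron-like cells 16 pericyte identity genes rose as a set (14 higher and 0 lower adjusted over the list alone, adjusted p = 1.62e-16, and adjusted p = 0.631 with an estimated correlation), at a median level of 0.91%, 0.245%, 3.24% and 3.17% of that in pericyte-like cells of WT 1, WT 2, Alk5iEKO 1 and Alk5iEKO 2.

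Pericyte-like cells made up 18.6% and 13.3% of WT and 30.2% and 33.4% of Alk5iEKO cells, a log2 fold change of the share of 0.99 ± 0.29 that did not pass (adjusted p = 0.144). Neuron-like cells made up 2.95% and 3.91% against 0.807% and 1.30% (−1.70 ± 0.38, adjusted p = 0.142). Endothelial-like cells made up 56.6% ± 1.78 (SD, n = 2) in WT and 48.6% ± 3.26 in Alk5iEKO (adjusted p = 0.593). Of 8 classes tested 0 passed in edgeR, and the exact permutation test of 2 against 2 libraries cannot give a p under 0.333. The sort sets how many cells of each class enter a library.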

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

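No test in this part was chosen only after its result was seen, although the patterns weighed here were. The genotype effect differed between endothelial-like and pericyte-like cells in 2626 genes by the interaction test. Among genes whose effect was higher in endothelial-like cells the difference on the log2 scale was 3.34 for Enpp2, 3.1 for Mt1, 2.89 for Adgrg1, 2.84 for Sult1a1 and 2.68 for Ifitm1. Among those whose effect was lower it was −5.90 for Htra3, −3.62 for Syt12, −3.57 for Chp2, −3.57 for Bpgm and −3.57 for Adamtsl2. No explanation was tested for these differences.

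Of 22 capillary markers 6 were lower and 1 higher in Alk5iEKO pericyte-like cells, with the list lost at an estimated correlation (adjusted p = 0.425), and a candidate explanation is endothelial RNA carried into them, since these genes also fell in endothelial-like cells. Of the genes lower in endothelial-like cells, the 40 whose WT pericyte level was by estimate mostly endothelial RNA had a median pericyte log2 fold change of −0.69 (quartiles −1.27 and −0.18) and the other 425 had −0.08, which is what that explanation needs. The estimate exceeded the measured level for several genes, so the 40 may include genes with less endothelial RNA. Exceptions are Slc22a8 and Rgcc, with 4.26% and 29.2% of their WT pericyte level from endothelial RNA and log2 fold changes of −1.17 (adjusted p = 0.00386) and −1.65 (0.0107) after subtraction of free RNA. For Slc38a5, Slc16a1, Slc16a4, Lrp8, Mfsd2a and Spock2 endothelial RNA was estimated at 59.6% to 236% of that level, and only Slc16a4 (−3.35, 0.0239) and Lrp8 (−7.29, 0.0217) had a value after subtraction. Their log2 fold changes before it were −1.49 and −1.84. Subtraction leaves no negative counts, so the sizes after it may reflect counts at the floor. An effect of the endothelial knockout on pericytes stays open, as untested.

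Pericyte identity genes were higher as a set in Alk5iEKO neuron-like cells, where 0 of 16 passed singly and the set was lost at an estimated correlation (adjusted p = 0.631). If pericyte RNA carried into these cells were the source, the ratio of the neuron-like to the pericyte level would be alike over these genes. Its standard deviation on the log2 scale was 1.67 in Alk5iEKO 1 and 1.61 in Alk5iEKO 2, between the bounds set for either answer, so pericyte RNA and expression in neuron-like cells cannot be told apart with 34 and 87 cells. An effect of genotype was not tested apart from this.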

How the results depend on the processing

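Results without cells rich in hemoglobin, with each library's mean removed before sub-clustering and with every sub-cluster named by its highest score come from tests chosen after seeing the data, and the other alternatives were planned. Of 2840 values of named genes under all alternatives, 2318 kept their direction and their side of the threshold, 450 kept their direction and no longer passed, 67 newly passed and 5 reversed. Nearly all that no longer passed did so without Alk5iEKO 1 (185) or Alk5iEKO 2 (181), where the spread comes from the WT libraries alone, or in capillary cells only (52). The values that reversed were Acvrl1 at −0.03 without Alk5iEKO 2 and −0.02 in capillary cells only, Angpt2 at −0.78 in capillary cells only, Rgs5 in endothelial-like cells at −3.20 with free RNA subtracted and Flt1 in pericyte-like cells at −0.25 with doublets kept. The cause was not tested here or below except where the construction shows it.

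Leaving out 1 library at a time gave 0 to 2703 genes in endothelial-like cells (1214 with all), 0 to 2131 in pericyte-like (996), 0 to 475 in smooth-muscle-like (1), 0 to 58 in fibroblast-like (0), 0 to 341 in astrocyte-like (3) and 0 to 167 in neuron-like cells (0). It gave 0 to 822 in arterial, 0 to 1100 in capillary, 0 to 1294 in venous, 354 to 2464 in tip-like and 95 to 1398 in proliferating cells, and 1603 to 2436 in the interaction. In each of these the counts without an Alk5iEKO library were below those without a WT library. Without a filter on low counts the numbers were 2634 in endothelial-like, 2670 in pericyte-like, 449 in smooth-muscle-like, 278 in fibroblast-like, 388 in astrocyte-like and 135 in neuron-like cells, and 726 in arterial, 29 in capillary, 1273 in venous, 2514 in tip-like and 1442 in proliferating cells. DESeq2 called 19 in smooth-muscle-like, 9 in fibroblast-like, 57 in astrocyte-like and 3 in neuron-like cells, 393 in capillary and 391 in proliferating cells, and 1074 in the interaction. Capillary cells alone gave 208 in place of 1214. With DESeq2's size factors astrocyte-like cells had 10. With doublets kept smooth-muscle-like cells had 9 and astrocyte-like cells 0, with at most 5% mitochondrial UMIs 10 and 32, with cells thinned to an equal median UMI count 9 and 17, and with free RNA subtracted smooth-muscle-like cells had 2. With subtypes named after removal of each library's mean, arterial cells had 490 and capillary cells 1355.

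With an estimated correlation 0 lists passed in any class in place of 10 in endothelial-like, 12 in pericyte-like, 7 in smooth-muscle-like, 8 in fibroblast-like, 8 in astrocyte-like and 7 in neuron-like cells, and with fry 0 passed in endothelial-like cells. In pericyte-like cells fry had adjusted p = 0.0316 for the lists of Notch, TGFβ target, barrier, capillary, dissociation, glycolysis, oxidative phosphorylation and reactive astrocyte genes and 0.0381 for inflammation genes. It did not pass the lists of pericyte identity (0.0966), matrix (0.0558), integrin (0.0966) and disease-associated microglia genes (0.201). In endothelial-like cells the list of proliferation genes turned from lower (adjusted p = 0.684) to higher without Alk5iEKO 1 (0.0252), and passed as lower without Alk5iEKO 2 (1.66e-04). Lists that newly passed there were homeostatic microglia (lower, 4.27e-10), pericyte identity (higher, 0.00937) and contractile smooth muscle genes (higher, 0.00937) without WT 1, and oligodendrocyte myelin genes (higher, 0.00997) without Alk5iEKO 2.

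Class shares on the log2 scale ranged without 1 library from −1.46 to 0.31 for astrocyte-like (−0.46 with all, reversed to 0.31 without WT 1 and 0.13 without Alk5iEKO 2), from −0.49 to 0.48 for fibroblast-like (0.01, reversed to −0.36 without WT 2 and −0.49 without Alk5iEKO 1) and from −5.06 to 4.28 for microglia-like cells (−4.08, newly passed without WT 1 at −5.06, adjusted p = 0.0140, and reversed without WT 2 to 4.28, since WT 2 held 746 of them). The arterial share of −0.03 reversed to 2.03 with all highly variable genes and 0.59 with library means removed, where it passed, and to 0.01 at 0.5 times the resolution, 0.20 without WT 2 and 0.06 without Alk5iEKO 2, within a range of −0.23 to 0.20 without 1 library. The proliferating share of −0.01 reversed to 0.28 with all highly variable genes, 0.03 without WT 2, 0.31 without Alk5iEKO 1 and 0.10 with every sub-cluster named by its highest score, from −0.45 to 0.31 without 1 library. The tip-like share of 0.44 newly passed with all highly variable genes (0.53) and with library means removed (0.28). The venous share of 1.62 no longer passed at 0.5 times the resolution (0.92), at 2 times the resolution (1.05), with doublets kept (0.43), with library means removed (0.26), and without Alk5iEKO 1 (1.66) or Alk5iEKO 2 (1.59), from 1.22 to 2.19 without 1 library. The capillary share of −2.39 no longer passed with library means removed (−0.24), which also removes true differences in composition. It passed at −0.79 with every sub-cluster named by its highest score (adjusted p = 0.0229) and at −4.11 to −2.25 under the other alternatives run. No paired analysis was possible because the labels pair no libraries. In neuron-like cells, with 34 cells in Alk5iEKO 1, 13.4% of 2-fold changes were recovered in simulation, so smaller changes can be missed.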

Other observations

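The list of glucocorticoid-responsive genes and the test of dissociation stress with its bound were chosen after the data were seen, and the other tests of this part were set before their results. Further gene groups changed in parts in endothelial-like cells without passing as sets. Of 33 tip cell markers 6 rose and 1 fell (9 and 2 adjusted over the list alone), with Mest at 2.38 ± 0.22, the vessel-destabilising ligand Angpt2 at 1.32 ± 0.15 and the laminin gene Lamb1 at −0.70 ± 0.09 (camera adjusted p = 0.290). Of 15 mesenchymal transition genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with the N-cadherin gene Cdh2 at −1.59 ± 0.09 and Vim at 1.04 ± 0.09 (adjusted p = 0.90). Of 24 hypoxia response genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with Ndrg1 at 2.26 ± 0.10 and the glycolysis regulator Pfkfb3 at −1.10 ± 0.13 (adjusted p = 0.779). Of 16 genes of iron and heme handling 2 rose and 3 fell (6 and 3 adjusted over the list alone), with the transferrin gene Trf at 1.19 ± 0.11 and the iron exporter gene Slc40a1 at −0.69 ± 0.09 (adjusted p = 0.598). Of 13 leaky vessel genes 2 rose and 1 fell (4 and 2 adjusted over the list alone), with the caveolin gene Cav1 at 1.63 ± 0.13 (adjusted p = 0.424). Of 19 junction genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with the VE-cadherin gene Cdh5 at 0.59 ± 0.11 and Cgnl1 at −0.76 ± 0.10 (adjusted p = 0.699).

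In pericyte-like cells some contractile and cell-cycle genes passed singly, and neither list passed as a set. Of 17 contractile smooth muscle genes 5 rose and 0 fell in edgeR (6 and 1 adjusted over the list alone), with Tagln at 1.20 ± 0.23, Tpm2 at 0.83 ± 0.09 and the desmin gene Des at 0.75 ± 0.10 (camera adjusted p = 0.257). Of 48 proliferation genes 11 rose and 6 fell (17 and 11 adjusted over the list alone), with the cyclin gene Ccnb2 at 1.15 ± 0.12 and the histone gene Hist1h1b at −2.09 ± 0.22 (adjusted p = 0.762). Of 33 interferon response genes 2 rose and 0 fell (2 and 1 adjusted over the list alone), with Irf1 at 1.36 ± 0.17 and B2m at 0.66 ± 0.11 (adjusted p = 0.739, with a median of −0.01 where the test's direction was up). Hmox1, the heme-degrading enzyme, rose by 2.19 ± 0.23.

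The red-cell enzyme gene Bpgm had 77.6 and 67.5 CPM in WT and 8.67 and 12.4 CPM in Alk5iEKO endothelial-like cells (−2.77, adjusted p = 0.00217), and 23.2, 18.1, 31.8 and 39.5 CPM in pericyte-like cells in the same order (0.79, adjusted p = 0.0479). The hemoglobin gene Hba-a1 had 976 and 416 CPM in WT and 24.1 and 118 CPM in Alk5iEKO endothelial-like cells.

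Of genes that glucocorticoids induce 12 were noticed first, Zbtb16, Lcn2, Mt1, Sult1a1 and Glul among them, of which 8 rose and 2 fell in endothelial-like cells, 2 rose in pericyte-like cells and 0 passed singly in the other classes. The 2 that fell in endothelial-like cells were Apod and Tsc22d3. Endothelial RNA carried into other classes is argued against, since in fibroblast-like cells it accounted for a median of 2.75% of their difference. Dissociation stress is left undecided, since the dissociation list had medians of 0.02, −0.01 and 0.13 in fibroblast-like, smooth-muscle-like and astrocyte-like cells and the lowest upper quartile was 0.15, above the bound set for excluding it. Glucocorticoid exposure may be an explanation, since the 19 listed genes not looked at beforehand passed upwards in 4 of 6 classes (adjusted p = 0.0390 in endothelial-like, 7.32e-05 in smooth-muscle-like, 9.36e-04 in fibroblast-like and 0.00119 in astrocyte-like cells), and not in pericyte-like (0.492) or neuron-like cells (0.992), while with an estimated correlation 0 classes passed, the smallest adjusted p being 0.251 in smooth-muscle-like cells. The fall of Apod and Tsc22d3 in endothelial-like cells runs against glucocorticoid exposure there. The labels name no such exposure, and a difference in handling between the genotypes' libraries cannot be told apart from the genotype.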
